A study of Homo sapiens with 16 samples.

How the data were processed

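Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which maps where a protein or histone mark sits on DNA, was deposited for 16 samples of 2 human cell lines. HepG2 is a hepatocellular carcinoma line and THLE-2 an immortalised, non-tumour liver epithelial line. The 8 immunoprecipitated (IP) libraries fall into 4 groups of 2 replicates: JARID2 in HepG2, and JARID2, EZH2 and the histone mark H3K27me3 in THLE-2. Each IP library has its own input library of sonicated chromatin, which makes 8 inputs. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 minutes, chromatin was sheared to 200 to 500 bp, and libraries were sequenced as paired 100-nt reads. The series describes the 2 replicates of a group as biological. The protocol text names a JARID2 antibody in 1 sample, HepG2 JARID2 replicate 1, while 15 samples carry the same general sentence on the antibody, so the target of each library was taken from its title and antibody tag. No EZH2 or H3K27me3 library of HepG2 is in the series.

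The submitters' processing notes name cutadapt, Bowtie2, MACS 1.4.2 and the genome build GRCh38; the versions of the first tools are not given in the sources used here. Per the file headers, MACS called peaks in each IP library against its own input from uniquely mapped reads, with a p cutoff of 1e-05 and at most 1 tag per position, and scaled the larger library down to the smaller. The authors deposited 1 peak list per IP library, and replicates were not pooled. Each deposited list gives, per the file headers, the tag count of a peak, a score of -10 times the log10 of the MACS p, the fold enrichment (a ratio of IP over local input background) and the false discovery rate in percent. The fold enrichment printed for a gene is that of its strongest peak in a list, as the authors computed it, and serves only to rank peaks within a list. Reads and coverage tracks were not used here, so a gene without a deposited peak is a gene where MACS called none, not a gene shown to be unbound.

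Peaks on chromosomes 1 to 22 and X were compared with the RefSeq annotation of GRCh38. The annotation at hand holds no strand, so the promoter window that had been planned around the transcription start became 2 kb on either side of both annotated gene ends. A gene counts for a group when a peak lies in this window in both replicates, over 19974 protein-coding genes. Genes with a shared end share a peak, and the peaks of both replicates may lie at opposite ends of a gene. Overlap between peak lists (at least 1 bp) was compared with 1000 random placements of the peaks of 1 list within their chromosome, in 100-kb bins that hold an annotated gene or a peak. The smallest p these placements can give is 0.001 one-sided and 0.002 two-sided. Overlaps between sets of genes, and 16 gene lists against all other protein-coding genes, were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg (BH) adjustment over the 6 pairs of groups and over the 64 tests of lists and groups. Odds ratios are given on the log2 scale with 95% intervals, and shares of peaks with Wilson 95% intervals, which cover counting error only. Each cell of an odds ratio had 0.5 added, which shifts it at small counts and can turn its sign. Fisher's exact test used the counts as they were. The share of JARID2 peaks at gene ends was compared between lines by exact permutation of the 4 libraries, where 3 splits exist and the smallest two-sided p is 0.3333. Genes and peaks within a library are not independent replicates, so these tests describe each pair of lists and not the spread between cultures.

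The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes of each group with a peak in both replicates whose worse rank of fold enrichment is best, the 10 such JARID2 genes found in HepG2 alone and in THLE-2 alone, up to 4 members of each list past the threshold in a group, and always the 4 HOX clusters, CDKN2A, CDKN2B, EZH2, JARID2, SUZ12 and EED. Not every gene the rule takes is printed. No gene had peaks of all 3 THLE-2 targets in both replicates, and the 1 gene with JARID2 and H3K27me3 is named in their place. The lists cover HOX cluster genes, developmental transcription factors outside the HOX clusters, hepatocyte function, liver transcription factors, epithelial-mesenchymal genes, tumour suppressor and hepatocellular carcinoma genes, WNT ligands and receptors, BMP, TGF-beta, FGF and hedgehog ligands, Polycomb group genes, neuronal channels and receptors, blood and endothelial markers, cell cycle and DNA replication genes, olfactory receptors, cytosolic ribosomal proteins, zinc finger genes, and replication-dependent histone genes. All members of the lists were matched in the annotation. Tests of these lists within single libraries (128 tests), of gene families (1012 tests) and of long non-coding RNA genes were chosen after the data were examined.

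Alternatives were a peak score of at least 100, a false discovery rate of at most 5%, equal numbers of top peaks per list, windows of 1 kb and 5 kb, an overlap of at least 50% of the shorter peak, a peak in either replicate, removal of regions with a peak in all 4 groups, placement of gene-end peaks at gene ends, replicates as blocks, and each replicate left out in turn. Whole genes, merged gene-end windows as units, shifts of whole lists along a chromosome and, for overlaps between lists of peaks, leaving out replicates were added after the data were examined. The planned stratification by CpG density was not run, since no genome sequence was at hand.

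The procedure was tested on simulated data. Of 200 randomly placed lists, 8 had a placement p under 0.05. The number of lists had been raised to 200 after the result of a smaller first run, with a higher share under 0.05, was seen. With 200 peaks set onto EZH2 peaks, 20 of 20 simulated lists passed, with a mean excess of 198 peaks. In the data, 73 EZH2 replicate 1 peaks overlapped THLE-2 JARID2 replicate 1, with 18.95 expected, and a planted number that small was not tried. Gene lists given a 4-fold weight were called in 84.2% and 89.5% of cases in gene sets of the size of the EZH2 and H3K27me3 sets, but in 5.33% and 10.3% in sets of the size of the HepG2 and THLE-2 JARID2 sets. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

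Depth after filtering, per the file headers, ran from 7.95 to 39.0 M tags in the IP libraries and from 13.4 to 31.1 M in the inputs. The peaks at gene ends, which number 139 in the smallest case, set the precision of each share, and 2 replicates per group set that of each difference between groups.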

Results

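Binding of 2 Polycomb proteins and their histone mark was mapped by ChIP-seq in a liver cancer line and a non-tumour liver line. EZH2 is the enzyme of Polycomb repressive complex 2 that methylates histone H3 at lysine 27, H3K27me3 is the mark it leaves, and JARID2 is a DNA-binding partner of the complex. Per the series, the question was how EZH2 and JARID2 change their binding in hepatocellular carcinoma. HepG2, the carcinoma line, has 2 JARID2 libraries, and THLE-2, the non-tumour line, has 2 libraries each of JARID2, EZH2 and H3K27me3. All positions are on GRCh38, and peaks are those the authors called with MACS for each library against its own input.

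The HepG2 JARID2 libraries held 7.95 and 14.6 M filtered IP tags and 15738 and 4090 deposited peaks for replicates 1 and 2. THLE-2 JARID2 had 11.7 and 13.0 M tags and 5356 and 5532 peaks. THLE-2 EZH2 had 29.6 and 32.4 M tags and 2112 and 3690 peaks. THLE-2 H3K27me3 had 39.0 and 38.1 M tags and 46198 and 90524 peaks. The authors' false discovery rate had a median of 1.29% in HepG2 JARID2 replicate 1, 15.8% and 44.2% in the THLE-2 JARID2 libraries, and 100% in the 5 other lists. Median peak widths were 604 and 541 bp for HepG2 JARID2, 598 and 605 bp for THLE-2 JARID2, 3012 and 1032 bp for EZH2, and 1494 and 1117 bp for H3K27me3.

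EZH2 in THLE-2 sat at the ends of genes for body plan and cell identity. Of 39 HOX cluster genes, which pattern the body axis, 24 (61.5%) had an EZH2 peak within 2 kb of a gene end in both replicates, against 4.77% of other protein-coding genes (log2 odds ratio 4.98, 95% interval 4.06 to 5.90, BH-adjusted p of Fisher's exact test, or exact BH p, = 1.0e-20). Of 184 developmental transcription factors outside these clusters, 121 (65.8%) had such a peak (log2 odds ratio 5.41, exact BH p = 7.1e-112). Examples are OLIG2, a factor of motor neuron and oligodendrocyte precursors, with fold enrichments of 15.17 and 11.07 in replicates 1 and 2, and PAX7, a factor of muscle stem cells, with 13.98 and 12.08. EZH2 peaks covered 53.8% and 65.2% of the HOXD cluster (chromosome 2, 176087487 to 176190907), and 49.7% and 61.0% of HOXA (chromosome 7, 27092993 to 27200091). They covered 38.8% and 65.0% of HOXC and 18.6% and 18.3% of HOXB.

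The 10 EZH2 genes ranked highest in both replicates included CELF4, LOC124905938, LGR6, FOXD3, FOXD2, ONECUT3, HOXD3, HOXD4 and SHISAL1. CELF4, a neuronal RNA-binding protein gene on chromosome 18 (37242844 to 37565798), had peaks at 37564139 to 37568786 and 37564241 to 37569337 with folds of 19.57 and 16.16. LGR6, a receptor for R-spondins (chromosome 1, 202193799 to 202319761), had 17.08 and 14.66. FOXD3, a forkhead factor of the neural crest, had 18.47 and 12.43. HOXD3 and HOXD4 shared a peak of 15.12 and 13.16.

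Signalling and neuronal genes were also among EZH2 targets in THLE-2. Of 98 neuronal channels and receptors, 35 (35.7%) had a peak in both replicates (log2 odds ratio 3.49, exact BH p = 3.6e-20), among them SLC6A5, a glycine transporter (15.12 and 10.41). Of 53 BMP, TGF-beta, FGF and hedgehog ligands, 15 (28.3%) had a peak (log2 odds ratio 2.99, exact BH p = 2.7e-07), with IHH at folds of 14.5 and 9.02 and INHBB at 12.19 and 8.56. Of 41 WNT ligands and receptors, 11 (26.8%) had a peak (log2 odds ratio 2.89, exact BH p = 2.1e-05), WNT3A with folds of 8.77 and 7.23. Of 30 liver transcription factors, 6 (20.0%) had a peak (log2 odds ratio 2.38, exact BH p = 0.0154), including GATA6 at 8.88 and 8.06. Of 52 epithelial-mesenchymal genes, 8 (15.4%) had a peak (log2 odds ratio 1.90, exact BH p = 0.0172), including OVOL1 at 16.43 and 9.49 and TWIST1, a driver of the mesenchymal state, at 8.21 and 7.84.

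Genes of hepatocyte function and several large gene classes had fewer EZH2 peaks than other genes. None of 122 hepatocyte function genes (exact BH p = 0.0215) and none of 392 olfactory receptors (exact BH p = 6.4e-08) had a peak in both replicates, and 4 of 517 zinc finger genes did (0.774%, log2 odds ratio -2.58, exact BH p = 1.8e-06). The lists of tumour suppressor and hepatocellular carcinoma genes (7 of 70, exact BH p = 0.215), Polycomb group genes (4 of 37, exact BH p = 0.248), and blood and endothelial markers (2 of 37, exact BH p = 1) did not pass the test. The same held for cell cycle and DNA replication (0 of 72, exact BH p = 0.139), cytosolic ribosomal proteins (0 of 82, exact BH p = 0.106) and replication-dependent histone genes (0 of 74, exact BH p = 0.139). Of 16 lists, 7 were higher and 3 lower, with the same counts of 7 and 3 when adjusted over the list alone, that is over the 16 lists of EZH2. CDKN2A and CDKN2B, cell cycle inhibitors of the INK4 locus, and EED and SUZ12, core subunits of the complex, had no peak at a gene end in any of the 8 IP libraries.

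**Figure D1:**
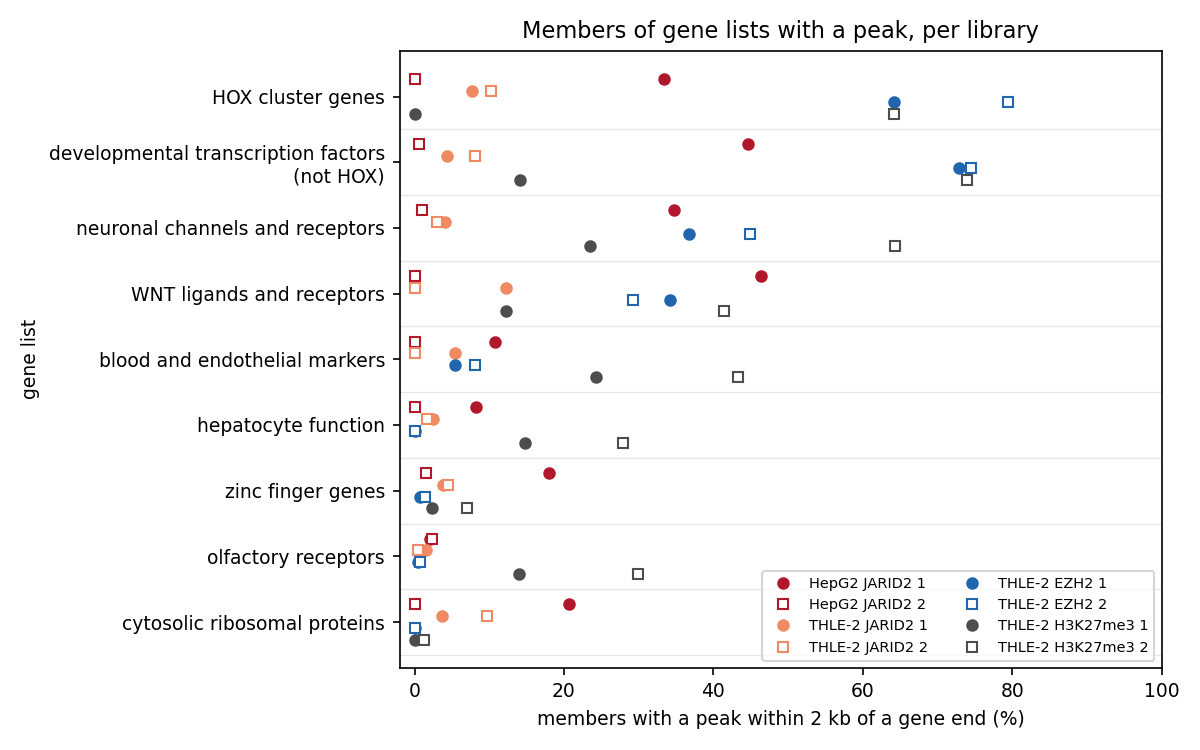
Share of the members of 9 gene lists with a peak within 2 kb of a gene end (x axis, percent), per IP library; filled circles are replicate 1, open squares replicate 2, and colours are the 4 groups. HOX cluster genes reach 64.1% in H3K27me3 replicate 2 and 0% in replicate 1, and developmental transcription factors 44.6% in HepG2 JARID2 replicate 1.

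H3K27me3 peaks found in both THLE-2 replicates were enriched at genes of blood, neurons and smell. Replicate 1 largely set these genes: 1349 of its 1538 genes also had a peak in replicate 2, which had 3819. In replicate 2 alone, developmental transcription factors reached 73.9%, neuronal channels and receptors 64.3%, HOX cluster genes 64.1% and olfactory receptors 29.8%. Of 98 neuronal channels and receptors, 23 (23.5%) had a peak in both replicates, against 6.67% of other genes (log2 odds ratio 2.12, 95% interval 1.45 to 2.79, exact BH p = 1.2e-06), with examples in SLC17A6, a glutamate transporter (folds 9.72 and 14.6), and GRIK2, a glutamate receptor (10.4 and 10.34). Of 37 blood and endothelial markers, 9 (24.3%) had a peak (log2 odds ratio 2.21, exact BH p = 0.00366). Among them were CD3D and CD3E, chains of the T cell receptor complex, at 21.08 and 13.58 and at 10.14 and 12.6. Of 392 olfactory receptors, 50 (12.8%) had a peak (log2 odds ratio 1.05, exact BH p = 9.5e-05), including OR6X1 at 14.97 and 15.74. Developmental transcription factors came to 22 of 184 (12%, log2 odds ratio 0.95, exact BH p = 0.0412), with GATA4 at 10.09 and 11.18 and MSX1 at 10.61 and 11.4.

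Genes of cytosolic ribosomal proteins, replication-dependent histones and zinc fingers carried fewer H3K27me3 peaks. None of 82 cytosolic ribosomal protein genes (exact BH p = 0.0275) and none of 74 replication-dependent histone genes (exact BH p = 0.0376) had a peak in both replicates, and 9 of 517 zinc finger genes did (1.74%, log2 odds ratio -1.99, exact BH p = 1.5e-06). Over the 16 lists, 4 were higher and 3 lower, and 6 and 4 when adjusted over the list alone. The 2 lists added as higher were hepatocyte function, with 15 of 122 genes (12.3%, exact BH p = 0.0431 over these 16), and BMP, TGF-beta, FGF and hedgehog ligands, with 8 of 53 (15.1%, exact BH p = 0.0431 over these 16). The strongest genes in both replicates included LOC124909494, EPPIN, EPPIN-WFDC6, ANKRD34B, PPP1R17, GALNT8, SIGLEC14, OR4D1 and VSX1. SIGLEC14, an immune cell lectin on chromosome 19 (51639478 to 51646825), had peaks at 51646813 to 51648254 and 51646832 to 51649051 with folds of 17.24 and 25.04. At LOC124909494, EPPIN, EPPIN-WFDC6, GALNT8 and OR4D1 the peaks of both replicates lay at opposite gene ends.

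The H3K27me3 replicates differed most at the HOX genes. In replicate 2, 25 of 39 HOX cluster genes (64.1%) had a peak and in replicate 1 none did, so that none passed in both. H3K27me3 peaks of replicate 2 covered 92.4% of HOXD, 89.1% of HOXA, 12% of HOXC and 33.8% of HOXB, while replicate 1 covered 0%, 0%, 0% and 13.3%. In replicate 2 alone, 136 of 184 developmental transcription factors (73.9%) and 16 of 30 liver transcription factors (53.3%) had a peak. Without replicate 1, 8 lists were higher in place of 4.

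**Figure D2:**
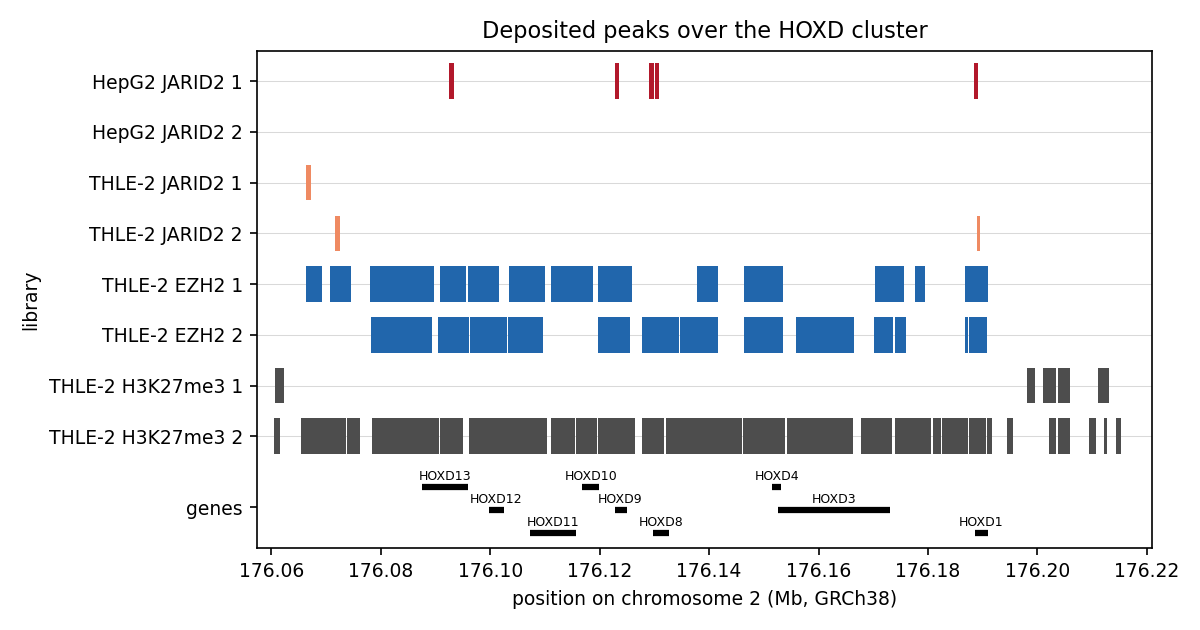
Deposited peaks (bars) of the 8 IP libraries over the HOXD cluster and 30 kb on either side on chromosome 2 (x axis, position in Mb, GRCh38), with HOXD genes below. EZH2 peaks cover 53.8% and 65.2% of the cluster, H3K27me3 peaks 0% in replicate 1 and 92.4% in replicate 2, and HepG2 JARID2 replicate 1 peaks 4.07%.

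EZH2 and its mark met at many of the same genes in THLE-2. Of 975 genes with EZH2 and 1349 with H3K27me3 in both replicates, 157 had both, where 65.8 were expected (log2 odds ratio 1.52, 95% interval 1.26 to 1.78, exact BH p = 2.1e-24). At several genes the peaks lay apart: at VSX1, a homeobox gene of the retina, EZH2 replicate 1 lay at 25080682 to 25085422 and H3K27me3 replicate 1 at 25068899 to 25075817, over opposite ends of the gene. With each gene-end window as its own unit, only 35 of 954 EZH2 windows held H3K27me3 in both replicates, where 43.3 were expected (log2 odds ratio -0.31, Fisher's exact p = 0.206), which turns the direction. H3K27me3 replicate 2 alone was at 749 of these 954 windows (78.5%, 134 expected) and replicate 1 alone at 38 (52.2 expected, log2 odds ratio -0.48, exact p = 0.0425). By gene, the log2 odds ratio was 4.60 without H3K27me3 replicate 1 and 1.37 without replicate 2. Of the peaks themselves, 66.4% of EZH2 replicate 1 peaks overlapped H3K27me3 replicate 2 (4.91 times random placement), and 9.95% overlapped replicate 1 (1.26 times). EZH2 replicate 2 gave 49.4% (4.36 times) and 12.4% (1.85 times).

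JARID2 in THLE-2 was found at few genes in both replicates. RNF130, a ubiquitin ligase gene on chromosome 5 (179911651 to 180071759), ranked first, with peaks at 180071878 to 180072545 and 180071805 to 180072640 and folds of 17.72 and 23.97. It was followed by OTULIN, a linear-ubiquitin protease gene (10.78 and 12.01), MOV10L1, ARFGAP3, OGDHL, ZNF598, LCMT2, MAPDA, NGB and SLC9A2. In all, 71 genes had a JARID2 peak in both replicates, from 840 and 875 genes per replicate, where 36.8 were expected by chance (log2 odds ratio 1.08, Fisher's exact p = 1.0e-07). At MOV10L1 the 2 peaks were at the same end, whereas at OGDHL they lay at opposite ends. Of the 16 lists, 0 passed Fisher's exact test in either direction, and 0 had an unadjusted p under 0.05. With 71 genes the test could decide little: simulated lists with a 4-fold weight were called in 10.3% of cases. Depletion could hardly pass, since even 0 of 392 olfactory receptors gave a Fisher's exact p of 0.407. In replicate 2 alone, 15 of 184 developmental transcription factors (8.15%) had a peak (log2 odds ratio 1.01, exact BH p = 0.0419). Olfactory receptors were lower in both libraries, with 6 and 2 of 392 (exact BH p = 0.0138 and 3.6e-05).

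THLE-2 JARID2 peaks met EZH2 more often than random placement gave. The 6 genes with both proteins in both replicates were FOXA2, GSC2, KIAA1549L, LOC124903566, NGB and RTN4RL2. At FOXA2, a pioneer factor of liver and endoderm on chromosome 20 (22580998 to 22585490), JARID2 had folds of 13.84 and 7.36 and EZH2 10.71 and 7.7. NGB encodes neuroglobin, and its JARID2 and EZH2 peaks lay apart, JARID2 at 77265918 to 77266727 and EZH2 at 77268986 to 77271982 in replicate 1. The overlap of 6 genes with 3.47 expected did not pass the test (log2 odds ratio 0.95, 95% interval -0.21 to 2.12, exact BH p = 0.241). It passed with the genes of either JARID2 library alone, at 0.81 (70 genes, 42.7 expected) without replicate 1 and 0.54 (57 genes, 41.0 expected) without replicate 2. Of the peaks, 328 overlaps over the 4 pairs of libraries were 3.84 times the random number (placement permutation p = 0.002, the smallest possible), and every pair lay between 3.69 and 4.17 times. With gene-end peaks placed at gene ends, the summed value was 2.44 times, and with the 2081 top peaks of each list 5.94 times.

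JARID2 and H3K27me3 in THLE-2 shared 1 gene, BACE2, an aspartyl protease gene on chromosome 21, where 4.80 were expected (log2 odds ratio -1.77, 95% interval -4.11 to 0.56, exact BH p = 0.183). JARID2 folds there were 10.03 and 7.76 and H3K27me3 folds 8.21 and 10.71. With single JARID2 libraries the log2 odds ratio was -0.72 without replicate 1 (37 genes, 59.1 expected) and -0.70 without replicate 2 (36 genes, 56.7 expected), both past the threshold, but -0.035 (13 genes, 13.6 expected) without H3K27me3 replicate 1. Over whole genes, a window that grows with gene length, it turned to 1.48, and gene length was not adjusted for. Peaks overlapped 1.18 times the random number (placement permutation p = 0.002), from 0.913 to 1.4 times per pair of libraries, and no longer passed without JARID2 replicate 1 (1.02, permutation p = 0.496) or without H3K27me3 replicate 2 (1.07, permutation p = 0.128). No gene carried JARID2, EZH2 and H3K27me3 in both replicates of each.

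JARID2 peaks of HepG2 were enriched at gene ends in replicate 1 and depleted there in replicate 2. In replicate 1, 27.1% of peaks (Wilson 95% interval 26.4% to 27.8%) overlapped a gene-end window, 3.81 times random placement, and in replicate 2, 3.41% (2.90% to 4.01%), 0.595 times. Only 45 of 4075 replicate 2 peaks (1.10%) overlapped replicate 1, 1.4 times random placement (one-sided placement permutation p = 0.021, two-sided BH p over 28 pairs of libraries = 0.0534). Among the 2081 top peaks of each list 17 overlapped, where 2.95 were expected. By gene, 4503 and 143 had a peak, and 33 had it in both, where 32.2 were expected (Fisher's exact p = 0.841). The highest of these 33 were SPOP, a substrate adaptor of a ubiquitin ligase (19.63 and 15.6), HDAC2, a histone deacetylase (18.24 and 12.28), XPO1, RBM44, RNF130, POU3F3, GRIN2B, HDAC8, CTF1 and ARFGAP3. At SPOP, HDAC2, RNF130 and ARFGAP3 the peaks of both replicates overlapped, whereas at XPO1, RBM44, POU3F3, GRIN2B and CTF1 they lay at opposite gene ends.

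Of the 16 lists, 0 passed in HepG2 JARID2 in both replicates by Fisher's exact test, and 0 had an unadjusted p under 0.05. With 33 genes this decides little, since simulated lists with a 4-fold weight were called in 5.33% of cases at this size. In replicate 1 alone, 82 of 184 developmental transcription factors (44.6% against 22.3%, log2 odds ratio 1.48, exact BH p = 3.6e-10) and 19 of 41 WNT ligands and receptors (46.3%, log2 odds ratio 1.58, exact BH p = 0.00368) had a peak. So did 16 of 37 Polycomb group genes (43.2%, exact BH p = 0.0141), 34 of 98 neuronal channels and receptors (34.7%, exact BH p = 0.0183) and 24 of 70 tumour suppressor and hepatocellular carcinoma genes (34.3%, exact BH p = 0.0478). JARID2 itself (fold 8.53) and EZH2 (fold 6.98) had a peak in this library, and JARID2 also in THLE-2 JARID2 replicate 1 (fold 6.88). In all, 4 lists were lower in replicate 1. They were hepatocyte function genes, with 10 of 122 (8.20%, log2 odds ratio -1.65), and olfactory receptors with 8 of 392 (2.04%, log2 odds ratio -3.75), as well as zinc finger genes (93 of 517, exact BH p = 0.0298) and replication-dependent histone genes (2 of 74, exact BH p = 1.1e-05). Replicate 2 passed for 1 list, with 9 of 392 olfactory receptors (2.30%, log2 odds ratio 1.84, exact BH p = 0.00668).

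Between the lines, JARID2 shared sites at 2 genes when a peak in every library was asked for. RNF130 and ARFGAP3, a regulator of Golgi transport on chromosome 22, had a peak at the same gene end in all 4 JARID2 libraries: RNF130 with folds of 62.87 and 9.35 in HepG2, and ARFGAP3 with 24.6 and 7.62 in HepG2 and 9.85 and 14.37 in THLE-2. These 2 genes shared by 33 HepG2 and 71 THLE-2 genes exceeded the 0.117 expected (log2 odds ratio 4.50, 95% interval 2.62 to 6.39, exact BH p = 0.0184). Without HepG2 replicate 1 (2.33, exact p = 0.0919) or without THLE-2 replicate 2 (1.39, exact p = 0.160) the overlap no longer passed. Without HepG2 replicate 2, 50 of the 71 THLE-2 genes were shared (16.0 expected, log2 odds ratio 3.03, exact p = 1.1e-17). Of the THLE-2 peaks, 4.37% of replicate 1 and 5.01% of replicate 2 overlapped HepG2 replicate 1, 4.91 and 5.79 times random placement. HepG2 replicate 2 gave 0.755 and 1.61 times, so the summed value of 4.58 times fell to 1.19 without HepG2 replicate 1.

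Few genes had JARID2 in both replicates of a single line. The 24 genes with peaks in HepG2 and in neither THLE-2 library include XPO1, a nuclear export receptor (16.56 and 11.34), RBM44, POU3F3, GRIN2B, HDAC8, CTF1, VRK3, ZNF473, REEP3 and VDAC1, of which VRK3 and ZNF473 share their peaks. They come from 33 HepG2 genes, near the 32.2 expected by chance between its replicates. At XPO1, RBM44, POU3F3, GRIN2B and CTF1 the peaks of both replicates lay at opposite gene ends, and at HDAC8 they did not overlap. The 21 genes with peaks in THLE-2 and in neither HepG2 library include ZNF598, LCMT2, SLC9A2, ZNF490, BACE2, AP4M1, MCM7, a replicative helicase subunit (12.42 and 7.53), FOXA2, SOHLH1 and SLC25A20. They come from 71 THLE-2 genes, where 36.8 were expected by chance between its replicates. HepG2 replicate 1 had a peak at 4503 of 19974 genes, so THLE-2 genes that passed by chance can also fall among the 21. Which of the 21 did so was not tested. Counts from single libraries were 3875 and 124 genes for HepG2 and 521 and 506 for THLE-2, and without HepG2 replicate 1 the THLE-2 count was 69. The share of JARID2 peaks at gene ends was 15.3% ± 16.8 (SD, n = 2) in HepG2 and 13.5% ± 0.161 (SD, n = 2) in THLE-2. The difference of 1.75 points was within the spread of the HepG2 replicates (exact permutation, two-sided, p = 1, smallest possible 0.3333).

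JARID2 peaks of HepG2 replicate 1 coincided with EZH2 sites of THLE-2. Of EZH2 replicate 1 peaks, 29.2% overlapped a peak of this library, 10.9 times random placement, and of EZH2 replicate 2 peaks, 17.5%, 9.16 times. CELF4 (fold 14.44), FOXD3 (12.9), FOXD2 (11.68) and IHH (10.86) were among genes with both. HepG2 replicate 2 did not differ past the threshold from random placement at EZH2 sites, at 0.541 and 0.601 times (two-sided permutation BH p = 0.138 and 0.137), or 1.21 and 0.985 times by the Jaccard index of covered bases. In both HepG2 replicates, only HEY2, a Notch target, and POU3F3, a factor of neural development, also carried EZH2 (1.61 expected, log2 odds ratio 0.63, 95% interval -1.23 to 2.49, exact BH p = 0.724). The gene overlap was 1.62 without HepG2 replicate 2 (443 genes, 220 expected) and -1.55 without replicate 1 (2 genes, 6.98 expected), and the summed peak overlap of 8.14 times fell to 0.574 without replicate 1 (two-sided placement permutation p = 0.0240). With gene-end peaks placed at gene ends it was 3.72 times, and with the 2081 top peaks of each list 17.1 times.

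HepG2 JARID2 peaks met THLE-2 H3K27me3 more or less often than random placement gave, depending on the pair of libraries. GRIN2B, a glutamate receptor gene, was the 1 gene with both (2.23 expected, log2 odds ratio -0.65, 95% interval -3.01 to 1.71, exact BH p = 0.724). Summed over 4 pairs of libraries, peaks overlapped 1.04 times the random number (placement permutation p = 0.0639), and 2.27 times with the 2081 top peaks of each list, past the threshold. The sum joins pairs that go opposite ways, each past the threshold (two-sided permutation BH p = 0.0028): HepG2 replicate 1 met H3K27me3 replicate 2 at 1.41 times and replicate 1 at 0.70 times, and HepG2 replicate 2 met them at 0.509 and 0.646 times. Without HepG2 replicate 2 the gene overlap lay below expectation (171 genes, 304 expected, log2 odds ratio -1.06). HepG2 replicate 1 alone gave -1.04 with H3K27me3 replicate 1 alone and 0.02 with replicate 2 alone (869 genes, 861 expected). Over whole genes, without adjustment for gene length, the overlap turned to 1.09. No mark or EZH2 library of HepG2 exists in the series, so these sites were compared across lines.

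Replicates shared positions to very different degrees. For EZH2, 1314 of 2081 replicate 1 peaks (63.1%) overlapped replicate 2, 75.3 times random placement, and for H3K27me3, 33284 of 46173 (72.1%), 6.29 times. For THLE-2 JARID2, 55 of 5351 (1.03%) overlapped, 3.54 times random placement. The placement permutation p was 0.001, the smallest possible, for these 3 groups. EZH2 peaks were at gene ends in 54.6% and 34.9% of cases, 5.56 and 4.23 times random placement, and THLE-2 JARID2 peaks in 13.4% and 13.6%, 2.04 and 2.19 times. H3K27me3 peaks were there in 4.67% and 6.10%, 0.602 and 0.828 times.

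**Figure D3:**
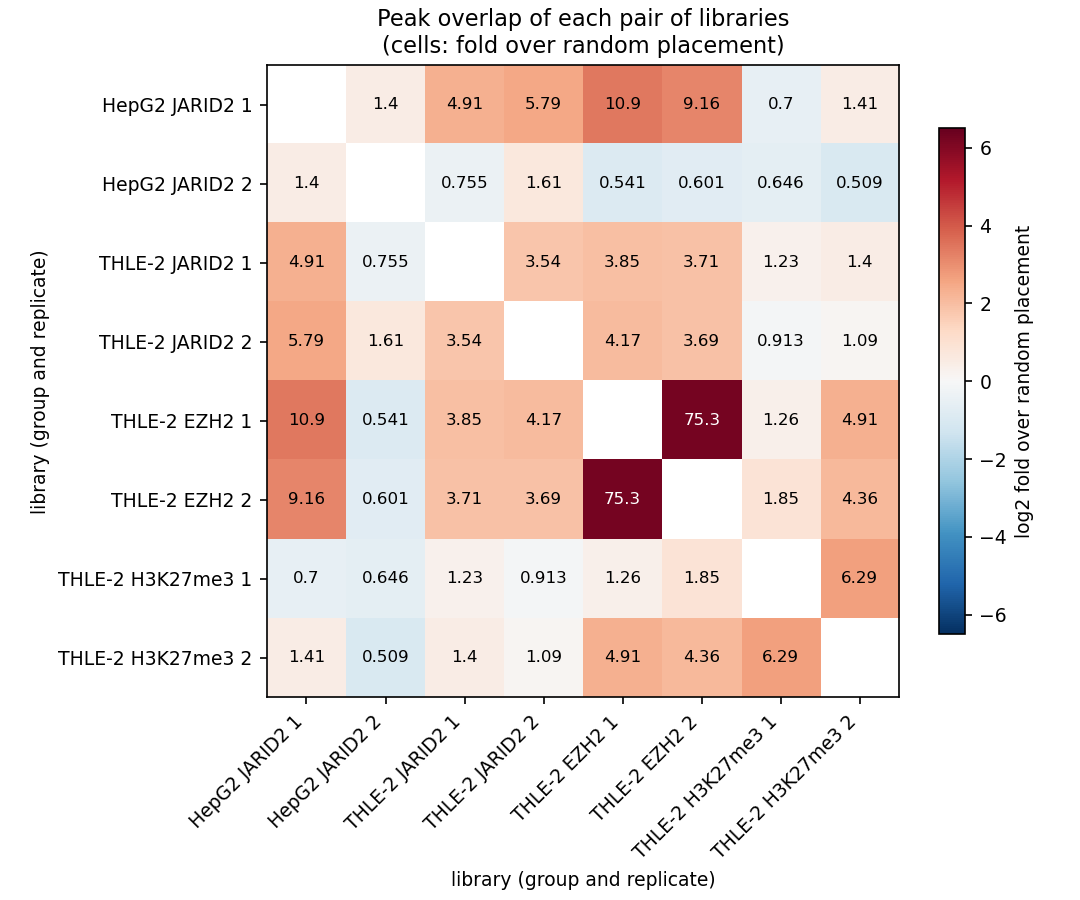
Overlap of each pair of the 8 IP peak lists as fold over random placement (cells; colour is the log2 of this fold, both axes are libraries by group and replicate). The EZH2 replicates stand at 75.3, the HepG2 JARID2 replicates at 1.4, and HepG2 JARID2 replicate 1 against EZH2 at 10.9 and 9.16.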

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

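The test of the THLE-2 JARID2 replicates with gene-end peaks placed at gene ends was written down before its result was seen, and the other tests below were chosen after. No biological explanation was tested for the differences between replicates, since the replicates of a group share their line and target.

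For neuronal channels and receptors, the share of genes with a JARID2 peak minus that of other genes was 12.2 and 0.306 points in the HepG2 libraries and -0.125 and -1.33 points in the THLE-2 libraries, a mean difference between lines of 6.98 points. It rests on HepG2 replicate 1, since the other libraries had a peak at 1, 4 and 3 of 98 genes and none passed Fisher's exact test (p = 0.506, 1 and 0.802). The difference between lines was not tested. Such opposite signs were seen in 1 of 16 lists, and how often chance gives them was not estimated. HepG2 replicate 2 had a peak at only 143 genes, so a list without a member there lies below other genes by construction. Peaks outside chromosomes 1 to 22 and X, which no comparison used, numbered 51 and 15 in HepG2 JARID2, 5 and 6 in THLE-2 JARID2, 31 and 53 in EZH2 and 25 and 63 in H3K27me3, above the limit of 3 that a count of 0 allows.

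H3K27me3 replicate 1 lacked peaks at EZH2 sites that replicate 2 marked strongly. Of the strongest 10% of replicate 2 peaks by score, replicate 1 held 17.8% of 1331 at EZH2 peaks (Wilson 95% interval 15.8% to 20.0%) and 83.3% of 6903 away from EZH2 and gene ends. Shallower sequencing of the IP library is argued against by a ratio of filtered IP tags of 1.03. MACS scaled the larger library down to the smaller, here the inputs with 25.1 and 31.1 M tags. Lower depth in the calling of replicate 1 would be expected to cost weak peaks first. At EZH2 peaks the share found fell from 38.7% in the next strongest 10% to 17.8% in the strongest. Away from EZH2 and gene ends it rose from 72.0% to 83.3%. For these peaks the values argue against lower depth as the only cause. An unrelated target is argued against by an overlap of both replicates of 6.29 times random placement. A loss of fragments with the base composition of gene ends could account for part of it, since at gene ends without EZH2 replicate 1 held 56.3% of 812 such peaks, but it stays open without the sequence.

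HepG2 JARID2 replicate 2 shared 1.10% of its peaks with replicate 1. Depth is argued against by 1.84 times as many filtered IP tags in replicate 2. Its peaks crowded in places, with 11.4% in the 26 densest 1-Mb windows against 5.16% for replicate 1 and 15.3% on chromosome 5, which holds 6.46% of the space, but outside these windows the shared part was still 1.11%. Another antibody could account for an overlap of 1.4 times random placement and stays open, since the protocol text names the antibody of replicate 1 only, although strong peaks were shared more often: 6 of the 100 strongest of replicate 1 against 0.244% of the rest, and 7 of the 100 strongest of replicate 2 against 0.956% (Fisher's exact p = 3.3e-07 and 9.2e-05).

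THLE-2 JARID2 replicates shared 1.03% of replicate 1 peaks. Noise among weak peaks may account for part of this: of the 100 strongest peaks of each list 16 in all were shared (7 and 9), against 0.914% and 0.866% of the rest (Fisher's exact p = 6.3e-05 and 5.4e-07), yet most of the strongest were not shared either, and shared peaks of replicate 1 had a lower median fold than the others (7.62 against 9.09). Sharing through enrichment at gene ends alone is argued against by an overlap of 3.07 times a placement that kept gene-end peaks at gene ends (55 against 17.9, placement permutation p = 0.001, the smallest possible). The placement drew from all gene ends of a chromosome alike, so a common preference for some gene ends stays open. Of the 100 strongest peaks of THLE-2 replicate 2, 41 overlapped HepG2 replicate 1, against 4.35% of the rest (Fisher's exact p = 4.1e-28).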

How the results depend on the processing

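Whole genes, merged gene-end windows, shifted lists and, for overlaps of peak lists, leaving out replicates were added after the data were examined. Over 244 alternatives, 174 left direction and side of the threshold (or the value within its spread) as they were, 5 were weaker, 23 stronger, 30 moved and 12 reversed; all 18 for the overlap of replicates stayed past the threshold in the same direction, 14 as the Jaccard index of covered bases and 4 as counts of peaks that overlap by at least 50% (main Jaccard values 2.60, 6.08, 324 and 12.1 times random placement for HepG2 JARID2, THLE-2 JARID2, EZH2 and H3K27me3). Counted as overlapping peaks, the HepG2 JARID2 replicates went from 45 (32.2 expected) to 17 (2.95 expected) with the 2081 top peaks of each list and 5 (0.138 expected) at a score of at least 100, and the THLE-2 JARID2 replicates from 55 (15.5 expected) to 19 (2.50 expected) and 2 (0.01 expected). The cause was not tested for any change below, except where the number of replicates or peaks changed by construction. The log2 odds ratio of THLE-2 JARID2 and EZH2 genes (0.95) passed the threshold at 2.16 with the 2081 top peaks of each list, 1.00 at 5 kb, 0.51 with a peak in either replicate and 1.45 over whole genes, and ran from 0.50 to 0.81 without single replicates. That of THLE-2 JARID2 and H3K27me3 (-1.77) reversed to 1.48 over whole genes and ran from -1.98 to -0.035. That of EZH2 and H3K27me3 (1.52) reversed to -0.31 with gene-end windows as units, which no longer join peaks at opposite ends of a gene, and ran from 1.37 to 4.60. That of JARID2 in both lines (4.50) ran from 1.39 to 3.03. That of HepG2 JARID2 and H3K27me3 (-0.65) reversed to 1.09 over whole genes and ran from -1.06 to -0.21. That of HepG2 JARID2 and EZH2 (0.63) was 1.39 with a peak in either replicate and 1.12 over whole genes, both past the threshold, and fell below expectation at 1 kb (0.43, 1 gene). It ran from -1.55 to 1.62, with 2 genes for 2.16 expected (0.18) without EZH2 replicate 1. The 24 HepG2 genes became 1 at a score of at least 100, 1 with equal numbers of top peaks, 15 at 1 kb, 67 at 5 kb, 3975 with a peak in either replicate and 327 over whole genes, and 25 to 3875 without single replicates. The 21 THLE-2 genes became 0 at a score of at least 100, 37 at 5 kb, 1006 with either replicate and 148 over whole genes, and 21 to 521. Lists higher in HepG2 JARID2 (0) became 5 with either replicate, 1 over whole genes and 1 to 4 without a replicate. Those in H3K27me3 (4) became 2 at a score of at least 100, 2 with equal numbers of peaks, 9 with either replicate and 5 to 8 without a replicate, while EZH2 (7) stayed between 6 and 8 and THLE-2 JARID2 at 0. The difference in the share of JARID2 peaks at gene ends (1.75 points) reversed to -8.70 at a score of at least 100, was 15.5 with equal numbers of top peaks, and without single replicates ran from -10.1 to 13.6. Peak overlap without single replicates ran from 1.19 to 5.35 for JARID2 in both lines, 0.574 to 9.93 for HepG2 JARID2 and EZH2, 0.560 to 1.24 for HepG2 JARID2 and H3K27me3, and 1.02 to 1.34 for THLE-2 JARID2 and H3K27me3. Overlap of HepG2 JARID2 and H3K27me3 (1.04) passed the threshold at 1.4 with a score of at least 100, 2.27 with equal numbers of peaks, 1.26 with an overlap of 50% and 1.06 with gene-end peaks placed at gene ends; that of THLE-2 JARID2 and H3K27me3 (1.18) reversed to 0.803 at a score of at least 100. With gene-end peaks placed at gene ends, HepG2 JARID2 and EZH2 fell from 8.14 to 3.72 times and THLE-2 JARID2 and EZH2 from 3.84 to 2.44 times, both still past the threshold.

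With same-numbered replicates as a block (Cochran-Mantel-Haenszel chi-square test), 4 overlaps that had not passed the threshold did so. Each gene counts in both blocks, so p can be too small. Single libraries gave larger sets (4503 for 33 genes), and the effect of the block alone was not tested. For THLE-2 JARID2 the log2 odds ratio was 0.54 with EZH2 and -0.22 with H3K27me3, and for HepG2 JARID2 1.48 and -0.97. EZH2 and H3K27me3 (3.29) and JARID2 in both lines (1.08) passed with and without the block. Both HepG2 values rest on replicate 1, which gave 1.56 with EZH2 replicate 1 and -1.04 with H3K27me3 replicate 1. HepG2 replicate 2 gave -1.12 with EZH2 replicate 2 (4 genes, 9.36 expected) and -0.28 with H3K27me3 replicate 2. HepG2 replicate 1 with H3K27me3 replicate 2 gave 0.02. The pairing rests on a shared number alone: differences between replicates correlated across genes by -0.0539 to 0.0421 between groups.

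The JARID2 overlaps of genes rest on 33 and 71 genes with a peak in both replicates. Gene overlaps with 0 shared genes and fewer than 1 expected were given no value, a rule set after they were seen: 5 at a score of at least 100, 3 with equal numbers of top peaks, 2 with gene-end windows and 1 at a false discovery rate of at most 5%. That limit leaves 0 peaks in 3 lists, 4 to 11 in 4 others and 15687 in HepG2 JARID2 replicate 1. The stratification by CpG density was not run.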

Other observations

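Outside the lists fixed in advance, gene families with at least 10 members were compared with all other protein-coding genes over 253 families and 4 groups, a set of tests chosen after the data were examined. EZH2 in THLE-2 was higher at 11 families, among them NKX homeobox genes (10 of 14, 71.4% against 4.83%, exact BH p = 5.6e-08), SOX factors (9 of 19, 47.4%, exact BH p = 1.8e-05), TBX factors (6 of 13, 46.2%, exact BH p = 0.00143) and KCNK potassium channels (7 of 15, 46.7%, exact BH p = 0.000298). H3K27me3 was higher at 14 families. Protocadherins of the PCDHGA family, which lie in 1 cluster with a common annotated end, had a peak in both replicates for 10 of 12 genes (83.3%, exact BH p = 5.6e-08). Keratins (KRT) had a peak in both replicates for 20 of 55 genes (36.4% against 6.67%, exact BH p = 5.9e-08), SIGLEC lectins for 9 of 12 (75.0%, exact BH p = 1.3e-06), kallikreins (KLK) for 8 of 15 (53.3%, exact BH p = 0.000200), CEACAM genes for 7 of 12 (58.3%, exact BH p = 0.000340) and late cornified envelope genes (LCE) for 7 of 19 (36.8%, exact BH p = 0.00823). Serotonin receptors (HTR) had it for 7 of 17 (41.2%, exact BH p = 0.00425) and POU genes for 6 of 19 (31.6%, exact BH p = 0.0428). Neighbours in such clusters can share a peak or a domain, so their counts are not independent. HepG2 JARID2 was higher at 1 family, the histone deacetylases HDAC2 and HDAC8 (2 of 11, exact BH p = 0.00823), and THLE-2 JARID2 at 0. The HepG2 call rests on 2 genes of a set of 33 that is near the 32.2 expected by chance between its replicates, and at HDAC8 the peaks of both replicates did not overlap.

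Long non-coding RNA genes had H3K27me3 peaks in both replicates more often than coding genes, and EZH2 and JARID2 peaks less often. Of 18177 such genes, 2140 (11.8%) had an H3K27me3 peak at a gene end in both replicates against 6.75% of coding genes (log2 odds ratio 0.88, 95% interval 0.78 to 0.98, Fisher's exact p = 7.2e-65), and 412 (2.27%) had EZH2 against 4.88% (log2 odds ratio -1.14). JARID2 was at 13 in HepG2 (0.0715% against 0.165%, log2 odds ratio -1.18, exact p = 0.0112) and 26 in THLE-2 (0.143% against 0.355%, log2 odds ratio -1.30, exact p = 3.7e-05). The HepG2 coding set of 33 genes is near the 32.2 expected by chance between its replicates, so its value says little about JARID2. The H3K27me3 sets required a peak in replicate 1, which lacked peaks at EZH2 sites. Single libraries were not compared here. Among EZH2 sites ranked highest were KCNQ1DN on chromosome 11 (folds 19.66 and 21.51), FOXD3-AS1 next to FOXD3 (18.47 and 12.43) and HOTAIRM1 in the HOXA cluster (17.55 and 11.3), which share peaks with coding neighbours in the latter 2 cases.

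A hypothesis set before its test is that strong EZH2 sites of THLE-2 may hold JARID2 in HepG2 replicate 1 more often than weak ones, beyond the effect of peak width; the pattern over whole peaks had been seen. In 1-kb windows around EZH2 replicate 1 summits, 39.7% of the strongest 20% by score (95% interval 35.1% to 44.4%) and 9.11% of the weakest 20% (6.71% to 12.3%) met a JARID2 peak of that library. EZH2 replicate 2 gave 35.6% and 2.06%. HepG2 replicate 2 met 0% of the strongest and 0.959% of the weakest windows of EZH2 replicate 1, and 0.137% of each in EZH2 replicate 2, so in HepG2 the pattern rests on 1 library. In THLE-2, windows of EZH2 replicate 2 met JARID2 replicate 1 in 2.88% of the strongest 20% (1.89% to 4.37%) and 0.137% of the weakest (0.0243% to 0.774%), and JARID2 replicate 2 in 4.12% (2.90% to 5.82%) and 0.687% (0.294% to 1.60%). With EZH2 replicate 1 the shares were 2.16% and 0.719%, and 3.12% and 1.44%, with intervals that overlap. H3K27me3 replicate 2 overlapped 76.9% of the strongest 20% of EZH2 replicate 1 peaks and 40.3% of the weakest, and H3K27me3 replicate 1 overlapped 1.92% and 18.2%.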
